A study of Drosophila melanogaster with 6 samples.

How the data were processed

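RNA of whole male larvae of the Drosophila melanogaster strain w1118 was measured on Affymetrix expression arrays, 3 arrays per maternal diet and 6 in all. Per the labels' protocols, total RNA was extracted with Tripure, treated with DNase, cleaned on a column and turned into biotinylated cRNA from 2 ug of total RNA. The values deposited by the authors are linear intensities, 1 for each of 18952 probe sets on each array. The summary method, background correction and scaling between arrays are not given in the sources used here. The array medians of the tested probe sets lay between 51.5 and 55.7, and no further scaling was applied. The upper quartiles were 218.2 to 224.2 in control and 212.8 to 216.3 in high-sucrose arrays, and the maxima 12783 to 13046 and 11771 to 12076. Bright probe sets thus lay lower in every high-sucrose array than in any control array at both points, in the direction of most calls, and 3 other scalings were tried. From 26.7% to 30.2% of the values of an array lay under 16. The number of arrays limits the precision.

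Samples were grouped by the maternal diet in their characteristics. The titles number the arrays of each group as biological replicates; how many larvae went into an array is not given in the sources used here. No array was left out. Control probe sets, 183 in number, were kept out of the tests, which leaves 18769. In the probe table, 13647 of these carry 1 gene symbol (11982 genes), 402 carry several genes and 4720 none. The symbols were matched to a RefSeq gene table of the assembly Release 6 plus ISO1 MT, which updated 0 symbols and left the gene IDs of 103 probe sets unmatched. That table served for names and for the order of neighbouring genes. Genes were named from probe sets of 1 gene, and a gene with several probe sets was represented in the list tests by the one with the highest mean.

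Differences were tested on log2(intensity + 16) in R 4.3.3 with limma 3.58.1, as a linear model of the 2 groups with empirical Bayes variances that follow mean intensity, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets (threshold 0.05). The residual degrees of freedom were 4 and the prior ones 5.16. Each log2 difference is the high-sucrose mean minus the control mean on this scale, which understates the change of dim genes. A tested value is called higher (rose) or lower (fell) where its adjusted p passed. An intensity compares 1 probe set between arrays and does not rank genes.

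Before the data were examined, 33 gene lists were fixed and then tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether a list moves 1 way by itself, were alternatives. The members of each list were also adjusted over the list alone. The lists cover glycolysis, the TCA cycle, oxidative phosphorylation, sugar transport and storage, digestive enzymes, sugar sensing, fat synthesis and lipases, and insulin signalling. They also cover hormones, glue, immunity, detoxification, antioxidant defence, heat shock, ribosomes, replication, chromatin, piRNAs, cuticle, chitin, amino acid metabolism and odorant binding. Markers of fat body, muscle, neurons, haemocytes, testis, Malpighian tubules and sex completed them.

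The genes named follow a rule of the same time. It takes up to 10 genes in each direction with the largest log2 difference among those called with 1 symbol and no overlap between groups. A direction with fewer was filled up to 10 by smallest p, as values that did not pass. It adds up to 3 genes with the smallest p in each list, and sex and stage markers as checks of the labels. Any other gene is said to have been chosen after its values were seen.

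Single measures were compared with exact permutation tests, two-sided, for which 3 against 3 arrays cannot go below 0.1. Alternatives were a replicate block, filters to the upper 50% and 70% of probe sets by mean, 3 other scalings, pseudocounts of 1 and 64, other variance models, array weights, a fold threshold of 1.5, an adjusted p threshold of 0.10, and each array left out in turn. The methods were tested on simulated data with normal noise, made from the real means and limma's fitted variances of the 18769 probe sets. Each of 10 simulations had 3 arrays against 3 and 200 changed probe sets, drawn from the brighter ones only. Limma recovered 63.3% of changes of 0.4 on the log2 scale, 93.0% of those of 0.6 and 99.5% of those of 1. Of its calls, 7.1% were false. No dim probe set was changed, so the recovered shares do not cover dim ones. The noise matched the fitted model by construction. Camera recovered 100% of the lists of 25 genes lowered by 0.2 and called 0.4% of the unchanged lists, in simulations with independent genes.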

Results

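The study asked how the sugar content of a mother's diet bears on gene expression in the next generation. Virgin females of w1118, a white-eyed laboratory strain, ate food with 0.15 M sucrose (control) or 1 M sucrose for 7 days and were mated to males kept on control food. Their offspring grew on control food at 25 C, with 12 h on fresh food before collection, and whole male larvae were taken. Each maternal diet had 3 arrays. The labels disagree on stage: titles and descriptions name wandering larvae, while the source, the characteristics and the design text name mid-stage larvae of the same instar. The titles also speak of the larvae as reared on the foods, while the characteristics and the design text assign the diets to the mothers, as is done here.

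Markers of sex and stage were read first as checks of the labels. The yolk protein genes, made by adult females, were dim in both groups: Yp1 had an intensity of 7.503 ± 2.08 in control and 9.20 ± 4.06 in high-sucrose arrays (mean ± SD, n = 3 each, as throughout), and Yp3 50.7 ± 8.36 and 56.3 ± 4.69. Yp2 was at 38.2 ± 16.5 and 40.3 ± 23.3. As genes of adult females, these cannot tell male from female larvae, so their low values do not check the label of sex. The glue gene Sgs3, active in salivary glands late in larval life, was near the top of the scale in both groups (10800 ± 765.5 and 11200 ± 199.8; adjusted p = 0.745). The larval serum protein gene Lsp2 was at 12490 ± 160.3 and 11380 ± 604.5 (adjusted p = 0.307), and the fat body gene Fbp1 at 4973 ± 894.2 and 4897 ± 678.9 (adjusted p = 0.976). The list of 8 sex markers had a median log2 difference of 0.027 (camera adjusted p = 0.515), and 0 of them passed by either adjustment. The genes roX1, roX2 and Eip74EF were not analysed here.

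Chd3, a chromatin remodelling helicase, rose from 9.28 ± 0.97 in control to 119.7 ± 41.6 in high-sucrose arrays, a log2 difference of 2.38 ± 0.20 (SE; adjusted p = 0.00188). Its control level lay under the lower quartile of every array (12.2 to 14.6), near background, so the size of the difference depends on the pseudocount. CG10073 rose from 76.3 ± 25.7 to 403.3 ± 119.3 (2.18 ± 0.23; adjusted p = 0.00578) and the carboxylesterase gene alpha-Est2 from 273.3 ± 31.9 to 518.3 ± 24.5 (0.89 ± 0.086; adjusted p = 0.00353). CG3819 fell from 2418 ± 151.8 to 700.8 ± 16.3 (-1.76 ± 0.058; adjusted p = 2.85e-06). CG7781 fell from 214.1 ± 17.99 to 63.3 ± 12.0 and the mucin gene Muc55B from 1437 ± 285.7 to 569.1 ± 57.5. Gr32a, a gustatory receptor gene, fell from 60.1 ± 6.14 to 23.0 ± 0.83 (-0.96 ± 0.12; adjusted p = 0.0121). With a pseudocount of 64 the log2 difference was 1.30 for the gene Chd3, -0.51 for the gene Gr32a and 0.49 for the gene CG9902, all past the threshold, and with a pseudocount of 1 it was 3.50 for the gene Chd3.

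**Figure D1:**
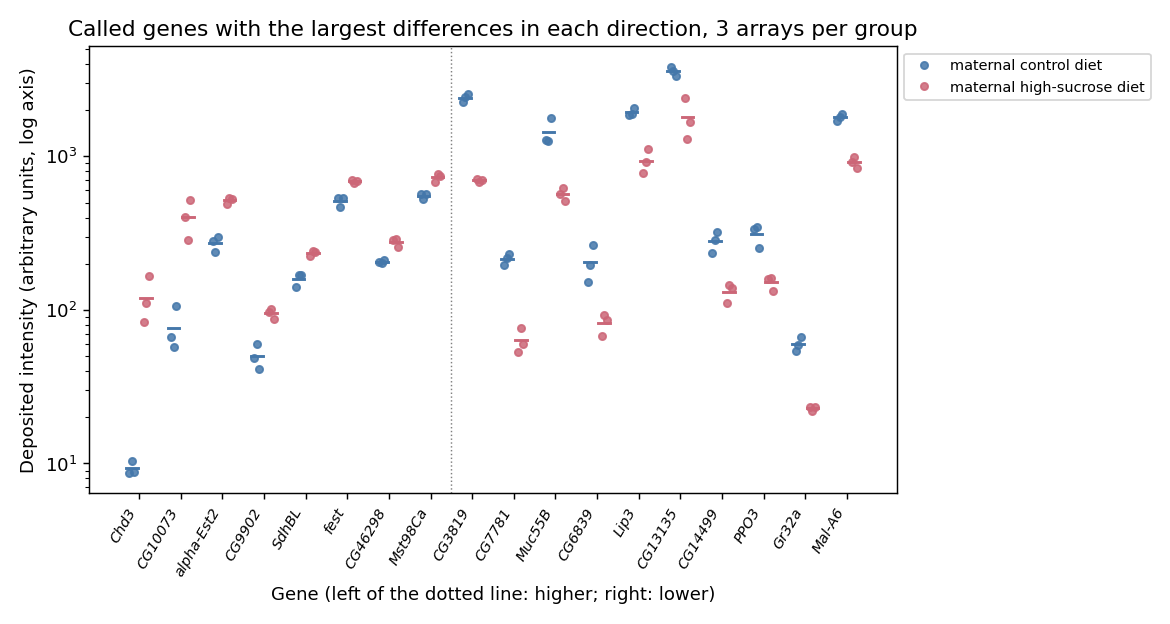
Deposited intensity on a log axis (arbitrary units) of the called genes with the largest differences in each direction, 8 higher and 10 lower; points are single arrays, 3 per group, and bars are group means, with the maternal control diet in blue and the maternal high-sucrose diet in red. Chd3 lies at 9.28 on average in control and at 119.7 in high-sucrose arrays, CG3819 at 2418 and 700.8, and the groups overlap in none of the genes.

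The other genes of this ranking that rose were CG9902, SdhBL, fest, CG46298 and Mst98Ca, with log2 differences from 0.39 to 0.76. Mst98Cb (0.45 ± 0.08; adjusted p = 0.0518) and CG6739 (0.51 ± 0.096; adjusted p = 0.0611) did not pass. The others that fell were CG6839, Lip3, CG13135, CG14499, PPO3 and Mal-A6, with log2 differences from -1.15 to -0.96. Among all 18769 probe sets tested, 10 were higher and 107 lower in the high-sucrose arrays, and 673 and 1652 were so at an unadjusted p under 0.05. The 107 lower probe sets had a median log2 difference of -0.55, and 99 of them carried 1 gene symbol. In all 117 the 3 arrays of each group did not overlap; 18.5% of all tested probe sets showed that, and chance gives 10%. Of the calls, 77.8% lay above the upper quartile of mean intensity.

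These counts depended on the scaling and on single arrays. Higher and lower probe sets numbered 17 and 76 under quantile scaling, 23 and 110 under median centring and 17 and 85 under cyclic loess, so that 18.3%, 17.3% and 16.7% of the calls were higher, against 8.5% without further scaling. With the replicate number as a block, 4 were higher and 59 lower. The counts were 2 higher and 11 lower without control 2, 3 and 28 without control 3, 3 and 39 without high-sucrose 1, and 5 and 30 without high-sucrose 3. Of 33 named genes that passed, CG3819, CG7781, Chd3, Jon74E, Mal-A6, Muc55B and alpha-Est2 passed whichever array was left out. CG10073 did not pass without control 2 (adjusted p = 0.07), and CG14499 and Gr32a without control 2 or control 3 (up to 0.102 and 0.0848). CG46298, CG9902, SdhBL and Mst98Ca did not pass without any 1 of the 6 arrays, with adjusted p up to 0.209, 0.135, 0.126 and 0.151. The gene fest passed only without high-sucrose 2 (otherwise up to 0.131). CG6839 did not pass without control 2, control 3, high-sucrose 1 or high-sucrose 3 (up to 0.135), and CG13135 without any control array or high-sucrose 3 (up to 0.164). Without the intensity trend in the variances, 1 probe set was higher and 3 were lower. All 117 kept their sign under the 3 other scalings. In the other alternatives, groups that do not overlap cannot change sign, so the kept signs there carry no information.

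Lists of digestive enzyme genes, and the list of lipases and fatty acid oxidation, lay lower in the offspring of high-sucrose mothers by camera with the preset correlation, but none of them passed with an estimated correlation (adjusted p = 0.341 for proteases, 0.341 for carbohydrases and 0.372 for lipases). By fry, which does not compare a list with other genes, all 3 passed as lower (adjusted p = 0.0177, 0.0207 and 0.0207). Of 25 measured gut proteases, the trypsin and Jonah families secreted into the midgut, 6 fell and 19 did not pass, and adjusted over the list alone, 15 fell. Jon74E fell from 5482 ± 107 to 3603 ± 163.6 (log2 difference -0.60 ± 0.049; adjusted p = 0.00188), Jon99Fi from 4590 ± 51.0 to 3117 ± 305 and Jon99Ci from 3255 ± 150.5 to 2374 ± 65.9. Of 12 digestive carbohydrases, which break starch and disaccharides into simple sugars, 4 fell and 8 did not pass, and adjusted over the list alone, 6 fell. The maltase gene Mal-A6 fell from 1797 ± 91.5 to 917.9 ± 74.8 (-0.96 ± 0.069; adjusted p = 0.00164), Mal-A1 from 3148 ± 382.7 to 1909 ± 59.5 and Amyrel, an amylase relative, from 3076 ± 186 to 2023 ± 238.6. Of 23 genes for lipases and fatty acid oxidation, 3 fell and 20 did not pass, and adjusted over the list alone, 9 fell. Those 3 were lipase genes: Lip3 fell from 1933 ± 121.2 to 940 ± 168.7 (-1.04 ± 0.11; adjusted p = 0.00637), CG6271 from 2043 ± 77.9 to 1485 ± 95.2 and CG6295 from 7772 ± 59.5 to 6375 ± 167.9.

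The protease list had a median log2 difference of -0.19 (camera adjusted p = 1.92e-09, adjusted p = 0.341 with an estimated correlation). The carbohydrase list had a median of -0.39 (1.29e-05, adjusted p = 0.341 with an estimated correlation). The lipase list had a median of -0.16 (camera adjusted p = 3.87e-05, adjusted p = 0.372 with an estimated correlation). Under quantile scaling, median centring and cyclic loess the lipase median was -0.086, -0.131 and -0.093. These 3 lists passed camera whichever array was left out. Jon99Ci, Lip3 and Mal-A1 did not pass without control 2 (adjusted p = 0.0848, 0.0783 and 0.0797), nor Jon99Fi without control 2 or control 3 (up to 0.102). Amyrel did not pass without control 2, control 3 or high-sucrose 3 (up to 0.13), CG6271 without control 2, high-sucrose 1 or high-sucrose 3 (up to 0.104), and CG6295 without any 1 array but high-sucrose 2 (up to 0.142).

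The list of detoxification genes lay lower as well by camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.451) or by fry (adjusted p = 0.0859). Of 41 measured members (cytochromes P450, glutathione transferases and related enzymes), 4 fell and 37 did not pass, and adjusted over the list alone, 20 fell. Cyp9b2 fell from 3833 ± 132.3 to 2796 ± 155.2 (-0.45 ± 0.055; adjusted p = 0.0115), Cyp304a1 from 196.2 ± 5.44 to 122 ± 7.31 and Cyp28d1 from 1250 ± 36.3 to 977 ± 17.8. The median log2 difference of the list was -0.27 (camera adjusted p = 3.51e-09; adjusted p = 0.451 with an estimated correlation). Of 15 antioxidant genes 1 fell and 14 did not pass, and adjusted over the list alone, 2 fell. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, fell from 605.4 ± 61.7 to 414 ± 41.5 (-0.53 ± 0.094; adjusted p = 0.0466). That list had a median of -0.095 (camera adjusted p = 0.0298; adjusted p = 0.517 with an estimated correlation) and did not pass without control 3 (0.162) or high-sucrose 3 (0.11). Cyp9b2 did not pass without control 2 or control 3 (up to 0.0924), Cyp304a1 without those or high-sucrose 3 (up to 0.0848), and Cyp28d1 and Gclc without those or either of high-sucrose 1 and 3 (up to 0.107 and 0.188).

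Of 26 genes of antimicrobial peptides and the immune response, 1 fell and 25 did not pass, and adjusted over the list alone, 4 fell. The gene that fell was PGRP-SC2, a peptidoglycan-degrading amidase, from 3216 ± 215.6 to 2101 ± 208.2 (-0.61 ± 0.077; adjusted p = 0.0125). Spn28Dc was at 127.6 ± 6.37 and 94.7 ± 1.41 (adjusted p = 0.0984) and TotC at 128.3 ± 43.8 and 61.6 ± 10.3 (adjusted p = 0.119). Of 20 markers of haemocytes, the larval blood cells, 2 fell and 18 did not pass, and adjusted over the list alone, 6 fell. PPO3, a prophenoloxidase of lamellocytes, fell from 312.3 ± 51.4 to 151.3 ± 15.2 (-0.96 ± 0.12; adjusted p = 0.0125), and the haemocyte surface gene He from 716.2 ± 45.2 to 540.4 ± 17.8 (adjusted p = 0.0282). The immune list had a median of -0.16 (camera adjusted p = 0.0131; adjusted p = 0.389 with an estimated correlation) and the haemocyte list of -0.13 (0.0352; adjusted p = 0.363 with an estimated correlation). Without high-sucrose 2 neither passed (0.14 and 0.0722), nor did the haemocyte list without high-sucrose 3 (0.122). PGRP-SC2 did not pass without control 2 (up to 0.104), PPO3 without control 2 or high-sucrose 3 (up to 0.102), and He without any 1 of the 6 arrays (up to 0.135).

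The lists of fat body, Malpighian tubule, cuticle and ribosomal genes passed camera on the lower side although 0 of their members passed over all probe sets. The 10 markers of fat body had a median log2 difference of -0.12 (camera adjusted p = 0.0131, adjusted p = 0.341 with an estimated correlation), with all 10 below 0. That median was -0.092 under median centring, -0.028 under quantile scaling and -0.019 under cyclic loess, with 6 of the 10 below 0 in the last 2. Gnmt was at 5485 ± 188 and 4665 ± 140.7 (adjusted p = 0.0799). The 16 markers of Malpighian tubules, the larval kidneys, had a median of -0.11 (0.0298; adjusted p = 0.517 with an estimated correlation); Prestin was at 180.2 ± 13.2 and 134.8 ± 1.99 (adjusted p = 0.0855). The 40 cuticle protein genes had a median of -0.12 (0.0352; adjusted p = 0.61 with an estimated correlation); Lcp65Ac was at 2984 ± 249.6 and 2433 ± 46.5 (adjusted p = 0.0924). Adjusted over the list alone, 1, 2 and 1 of these members fell, against 0, 1 and 0 under each of the 3 other scalings. By that adjustment 1 Malpighian gene rose under quantile scaling and cyclic loess. The 29 cytosolic ribosomal protein genes had a median of -0.085 (1.29e-05; adjusted p = 0.455 with an estimated correlation), with 0 falling adjusted over the list alone, and the median was 0.01 under cyclic loess. RpL36A was at 7800 ± 133.2 and 7127 ± 101.6 (adjusted p = 0.25). The Malpighian list did not pass without control 1, control 3 or high-sucrose 3 (0.0847, 0.0702 and 0.211), nor the cuticle list without control 3, high-sucrose 1 or high-sucrose 3 (0.173, 0.132 and 0.0985). Under quantile scaling the ribosomal, fat body, Malpighian, antioxidant and haemocyte lists did not pass (adjusted p from 0.126 to 0.801).

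The list of testis genes lay higher in the offspring of high-sucrose mothers by camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.341) or by fry (adjusted p = 0.0859). Of 31 markers of testis and male germline, 1 rose and 30 did not pass, and adjusted over the list alone, 4 rose. The 31 include svp, which entered through a synonym of a listed name and was not written in the list. Mst98Ca, which encodes a protein of the sperm tail, rose from 555.3 ± 23.3 to 731.6 ± 46.8 (0.39 ± 0.064; adjusted p = 0.0357). Its relative Mst98Cb was at 214.6 ± 12.97 and 298.5 ± 24.7 (adjusted p = 0.0518), and ocn at 803.1 ± 63.3 and 974.2 ± 25.5 (adjusted p = 0.119). The median log2 difference was 0.17 (camera adjusted p = 5.67e-08, adjusted p = 0.341 with an estimated correlation). Of 12 glue protein genes of the salivary gland 0 passed by either adjustment, that over all probe sets or adjusted over the list alone. Under quantile scaling, median centring and cyclic loess, 1, 0 and 3 of them rose adjusted over the list alone, and the list medians were 0.285, 0.225 and 0.278. Sgs1 was at 2710 ± 336.7 and 3354 ± 241.9 (adjusted p = 0.202). The glue list had a median of 0.20 (camera adjusted p = 0.0298; adjusted p = 0.517 with an estimated correlation) and did not pass without control 3 (0.0806) or high-sucrose 1 (0.0818). Mst98Ca passed in none of the fits that left out an array (up to 0.151).

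**Figure D2:**
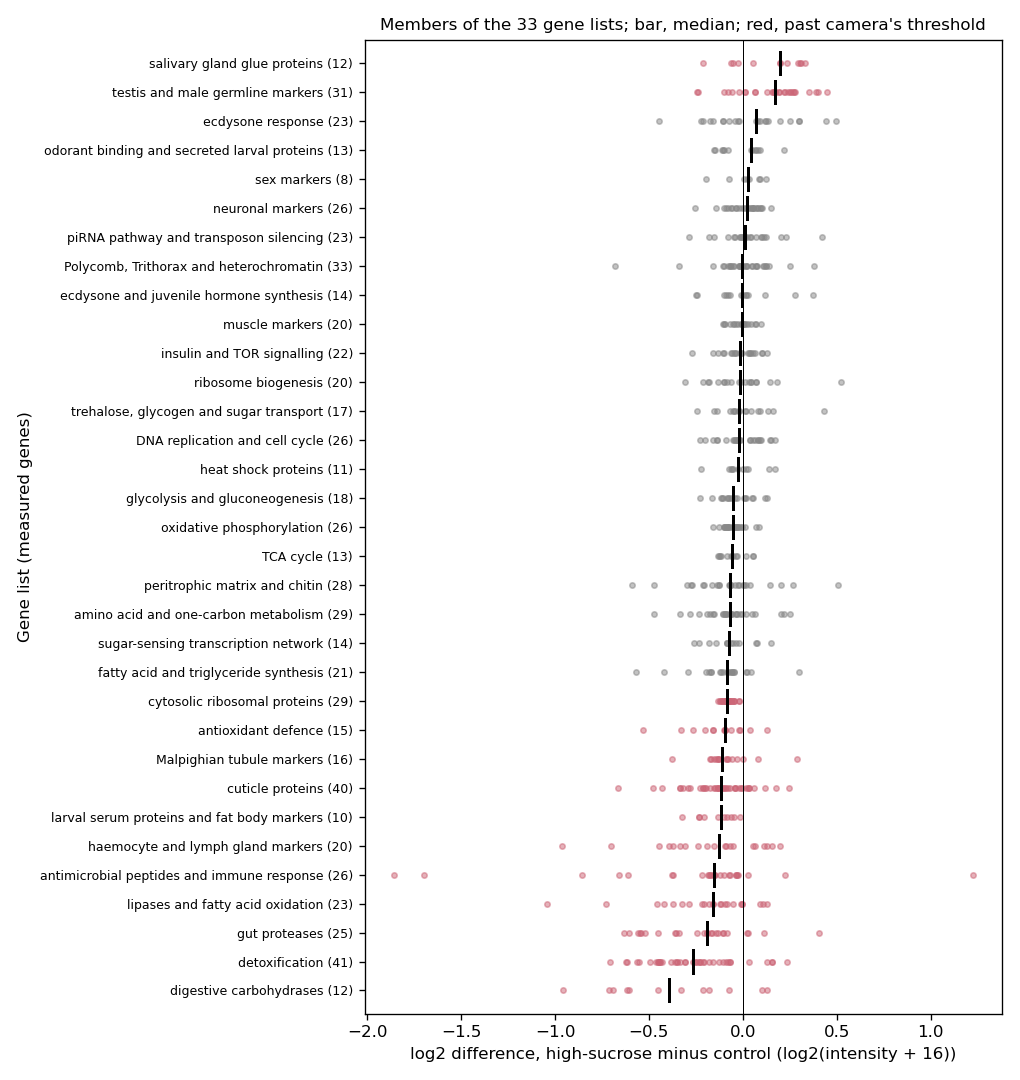
Log2 difference (high-sucrose minus control, of log2(intensity + 16)) on the x axis for the measured members of the 33 gene lists on the y axis, with the number of members in brackets; points are genes, bars are medians, and red lists passed camera with the preset correlation. The carbohydrase median lies at -0.39 and the testis median at 0.17, single genes reach from -1.86 to 1.23, and the ribosomal median, -0.085 as plotted, was 0.01 under cyclic loess.

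Apart from the list of lipases and fatty acid oxidation, the lists of sugar and fat metabolism did not pass camera. The median log2 difference was -0.051 over 18 genes of glycolysis and gluconeogenesis (adjusted p = 0.512), -0.056 over 13 of the TCA cycle (0.393) and -0.055 over 26 of oxidative phosphorylation (0.191). It was -0.018 over 17 genes of trehalose, glycogen and sugar transport (0.679), -0.073 over 14 of the sugar-sensing network (0.515), -0.013 over 22 of insulin and TOR signalling (0.771) and -0.07 over 29 of amino acid and one-carbon metabolism (0.148). Of 21 genes of fatty acid and triglyceride synthesis (median -0.084; 0.0691) 1 fell: Dgat2, which makes triglyceride from diglyceride, from 207.6 ± 15.5 to 134.8 ± 7.80 (-0.57 ± 0.083; adjusted p = 0.024). Treh, which splits the blood sugar trehalose, was at 1066 ± 48.5 and 895.8 ± 15.2 (adjusted p = 0.0912), and Akh, the hormone that mobilises stored sugar and fat, at 40.3 ± 3.195 and 59.98 ± 4.05 (adjusted p = 0.151). Adjusted over the list alone, Treh fell and Akh rose, Pepck2 and Gnmt each fell in their lists, and 2 fat synthesis genes fell. By that adjustment, under each of the 3 other scalings, 0 genes of the sugar transport, glycolysis and amino acid lists fell, and 1 of fat synthesis. In the sugar transport list 1 gene rose under median centring and cyclic loess and 0 under quantile scaling, where 1 TCA cycle gene rose. In the other lists of this group 0 members passed over all probe sets. Dgat2 did not pass without control 2, control 3, high-sucrose 1 or high-sucrose 3 (up to 0.12). Without high-sucrose 2 the lists of the TCA cycle (0.028), oxidative phosphorylation (0.00142) and fat synthesis (0.00302) passed, as did the last 2 without control 1 (0.0229 and 0.0475).

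Of the remaining lists, 28 genes of the peritrophic matrix and chitin had a median of -0.068 (camera adjusted p = 0.0818). One of them, the chitinase gene Cht4, fell from 3232 ± 217.8 to 2150 ± 274.2 (-0.59 ± 0.089; adjusted p = 0.0265), and adjusted over the list alone, 5 fell. The 23 ecdysone response genes had a median of 0.07 (0.0973), the 14 genes of ecdysone and juvenile hormone synthesis -0.004 (0.626) and the 11 heat shock genes -0.025 (0.904). Medians were -0.015 for 20 genes of ribosome biogenesis (0.771), -0.022 for 26 of replication and cell cycle (0.432), -0.003 for 33 Polycomb, Trithorax and heterochromatin genes (0.191) and 0.011 for 23 piRNA pathway genes (0.157). Psc, a Polycomb gene, was at 63.2 ± 4.84 and 34.1 ± 11.4 (adjusted p = 0.12). The 20 muscle markers had a median of -0.005 (0.841), the 26 neuronal markers 0.023 (0.195) and the 13 odorant binding and secreted larval proteins 0.045 (0.904). In these lists other than the chitin list 0 members passed by either adjustment, that over all probe sets or adjusted over the list alone. Under each of the 3 other scalings, 3 ecdysone response genes rose adjusted over the list alone. Under median centring 1 ecdysone response gene and 1 Polycomb list gene fell by that adjustment. Cht4 did not pass without control 2, control 3, high-sucrose 1 or high-sucrose 3 (up to 0.135). The chitin and ecdysone response lists passed without high-sucrose 2 (0.00818 and 0.0491), and these 2 and the replication and neuronal lists without control 2 (0.0146, 0.0174, 0.0377 and 0.0174). Under quantile scaling the muscle list passed as higher (0.0263).

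Across the 33 lists, 11 were lower and 2 higher by camera with the preset correlation, and 6 passed by fry, all lower. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05. The lists called higher were 5 without control 2, 1 without control 3 and 1 without high-sucrose 1, and those called lower were 7 without high-sucrose 3 and 6 under quantile scaling. Another division of the 6 arrays into 3 and 3 also gave 13 lists past camera. The median, the mean and the camera direction differed in sign in 9 lists that did not pass: sugar transport and storage, insulin, hormone synthesis, heat shock, ribosome biogenesis, replication, Polycomb, muscle and odorant binding. Camera measures a list against all other genes, and the median log2 difference of all probe sets was -0.034. With other scalings the median changed sign in 13 of the 20 lists that did not pass and in 1 of the 13 that did, the ribosomal list.

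The arrays of both groups were close to each other. Pearson correlations over probe sets lay between 0.990 and 0.993 within groups and between 0.988 and 0.992 between them, and the first principal component, with 28.3% of the variance, separated the groups. The second, with 25.4%, cut across them. Control 1, control 3 and high-sucrose 3 scored 12.4, 11.77 and 11.77 on it. Control 2, high-sucrose 1 and high-sucrose 2 scored -13.58, -17.58 and -4.77. The ratio of the 3' to the 5' actin control, a measure of RNA integrity, was 6.65 ± 1.26 in control and 8.54 ± 1.02 in high-sucrose arrays (exact permutation p = 0.2). The same ratio was 7.64 ± 1.17 and 8.55 ± 0.15 for eIF-4a (p = 0.3), 1.95 ± 0.18 and 1.97 ± 0.052 for GAPDH (p = 0.9) and 2.67 ± 0.73 and 2.12 ± 0.37 for 18S rRNA (p = 0.3), all by exact permutation. The 3' control of 18S rRNA was 4840 ± 176 and 4290 ± 251, with no overlap (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), while the 5' control was 1930 ± 674 and 2090 ± 497 (exact permutation p = 0.7) and the middle one 3260 ± 461 and 3810 ± 737 (exact permutation p = 0.4).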

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

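The alternatives were planned, and the cause of a change was not tested unless the alternative itself shows it, as fewer arrays or another threshold do. All 117 called probe sets kept their sign in every alternative that tested them. Among pairs of a named called gene and an alternative, 471 of 625 stayed past the threshold, 154 did not and 0 reversed, and other named genes newly passed in 43 pairs. Signal over background limits the dim probe sets, since 26.7% to 30.2% of an array's values lay under 16.

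Against 10 higher and 107 lower probe sets, counts were 1 and 3 without the variance trend, 19 and 176 with robust variances, 5 and 46 at 1.5-fold or more, and 36 and 228 at an adjusted p under 0.10. Higher probe sets were 17 under quantile scaling, 23 under median centring and 17 under cyclic loess, and lower ones then 76, 110 and 85. Leaving out 1 array gave 2 to 9 higher and 11 to 154 lower. With the replicate number as a block, 4 were higher and 59 lower. The numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.072, 0.025 and -0.014, and no array correlated best with its own number. Control 1 correlated best with high-sucrose 3 (0.241), control 2 with high-sucrose 1 (0.188) and control 3 with high-sucrose 2 (0.161). Whether a pairing other than by number exists was not tested.

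Some named genes that did not pass changed sign. Mf had a log2 difference of 0.0018 under cyclic loess, and Argk1 0.0191 under quantile scaling and 0.0279 under cyclic loess. Fbp1 had 0.0992 (quantile), 0.0113 (median centring), 0.071 (cyclic loess) and 0.0369 (array weights), and Yp2 -0.0912 with array weights. With 1 array left out, Fbp1 ranged from -0.1647 to 0.1028, Yp2 from -0.2935 to 0.2684, Yp1 from -0.0249 to 0.2077, Sgs3 from -0.0046 to 0.0935 and Sxl from -0.1364 to 0.0071.

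Lists past camera numbered 11 lower and 2 higher. With an estimated correlation 0 lower and 0 higher passed, with adjusted p of 0.341 (proteases, carbohydrases, testis, fat body), 0.363 (haemocyte), 0.372 (lipases), 0.389 (immune), 0.451 (detoxification), 0.455 (ribosomal), 0.517 (antioxidant, glue, Malpighian) and 0.61 (cuticle). By fry 6 lower and 0 higher passed, with adjusted p of 0.0177 (proteases, haemocyte), 0.0189 (fat body) and 0.0207 (carbohydrases, lipases, ribosomal). Fry gave 0.0859 for detoxification and testis, 0.105 immune, 0.136 antioxidant, 0.351 glue, 0.0569 Malpighian and 0.234 cuticle. By fry the direction turned for insulin (0.527), hormone synthesis (0.902), heat shock (0.527), ribosome biogenesis (0.59), replication (0.967) and muscle (0.902), which passed in neither test.

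Under quantile scaling 6 were lower. The adjusted p was then 0.209 (fat body), 0.296 (antioxidant), 0.801 (ribosomal), 0.126 (haemocyte) and 0.302 (Malpighian), muscle passed as higher (0.0263), and the direction of glycolysis (0.302), TCA cycle (0.306), oxidative phosphorylation (0.216) and odorant binding (0.463) turned. Over the upper 50% of probe sets, antioxidant (0.075), haemocyte (0.19) and Malpighian (0.075) did not pass, Polycomb did (0.043), and sugar transport turned (0.97). With the mean of all probe sets of a gene, chitin passed (0.0291). With the replicate block Malpighian did not pass (0.0772), odorant binding turned (0.901), and no other list changed its call.

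With 1 array left out, 7 to 13 lists were lower and 1 to 5 higher. Adjusted p then ran from 0.00903 to 0.0818 for glue, 1.23e-06 to 0.14 immune, 0.00603 to 0.162 antioxidant, 0.00818 to 0.173 cuticle, 0.013 to 0.122 haemocyte and 0.0174 to 0.211 Malpighian. For lists that did not pass it ran from 0.0919 to 0.953 (glycolysis), 0.028 to 0.995 (TCA cycle), 0.00142 to 0.953 (oxidative phosphorylation), 0.219 to 0.914 (sugar transport), 0.00302 to 0.255 (fat synthesis) and 0.338 to 0.953 (insulin). It ran from 0.0174 to 0.263 (ecdysone response), 0.795 to 0.953 (heat shock), 0.422 to 0.914 (ribosome biogenesis), 0.0377 to 0.806 (replication), 0.00818 to 0.299 (chitin), 0.244 to 0.899 (muscle), 0.0174 to 0.795 (neuronal) and 0.802 to 0.995 (odorant binding).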

Other observations

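In this part the families, the genes named and the tests were chosen after the values were seen, apart from the test of 13 other gut genes against the median of 3 lists and the count of lists in other divisions of the arrays. The 12 gene families looked at were picked by symbol after the calls were seen, so counts of the 3 with more than 1 called gene are given without a test for an excess. Of 32 tetraspanin genes, membrane scaffold proteins, 4 fell: Tsp42Er from a mean intensity of 610 to 401, Tsp42Ec from 1420 to 1040, Tsp29Fb from 2370 to 1830 and Tsp29Fa from 2990 to 2370. Of 83 cytochrome P450 genes 4 fell, among them Cyp9f2 from 3610 to 2690; 66 of the 83 had a log2 difference below 0. Of 8 alpha-esterase genes alpha-Est2 rose while its neighbour alpha-Est5 fell from 619 to 417 (log2 difference -0.55 ± 0.083 SE, n = 3 arrays per group).

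The protease, carbohydrase and lipase lists lay lower, with a median log2 difference of -0.19 over 60 genes (95% bootstrap interval over genes -0.31 to -0.15), of which 13 fell, and with adjusted p = 0.341, 0.341 and 0.372 with an estimated correlation; the lipase list also holds fatty acid oxidation genes. Scaling of bright probe sets as the whole change is argued against by cyclic loess, which left a median of -0.12 (interval over genes -0.24 to -0.086). Whether scaling makes up at least 0.5 of the change (-0.095) cannot be told apart, as that interval spans this value. Intervals over genes hold no spread between arrays, which all genes share, so they describe these 6 arrays only. A gut share lowered equally for all genes is argued against as the whole change, provided that each gene is read from gut RNA alone, which was not tested. The 21 protease and carbohydrase genes with intensities from 500 to 4000 ranged from -0.96 to 0.41 (Cochran's Q of 14.55 per degree of freedom). Other divisions of the arrays gave at most 3.10. They count the group difference as spread between arrays, which lowers their Q, so they are no reference for it. For a smaller gut share as at least 0.5 of the change, 13 other gut genes were fixed before their test. They were junction and structural proteins, transcription factors, hormones and an enzyme, with intensity up to 1222 and 0 in other lists. In whole larvae their RNA need not come from the gut alone, which was not tested. Their median was -0.12 (-0.26 to -0.099), and 12 of them lay below 0. By the bound set before the test, -0.095, the prediction of a smaller gut share as at least 0.5 of the change was met. Under cyclic loess the digestive median moved from -0.19 to -0.12, and the 13 genes were not read there. Their median thus cannot tell a smaller gut share from scaling of bright probe sets. The interval of the 13 genes was not clear of -0.107, a bound without the lipase list that was added after the values were seen. The 7 junction and structural genes alone, also picked afterwards, had -0.10 (-0.12 to -0.053), so the size of the gut share stays open. A difference in stage stays open, because the glue list (0.20; -0.039 to 0.30) and the ecdysone list (0.07; -0.11 to 0.12) had wide intervals and several glue genes were near the top of the scale, and the mothers' diet itself was not tested apart from these.

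The testis list lay higher, with a median log2 difference of 0.17 over 31 genes, of which 1 rose, in no fit that left out an array, and with adjusted p = 0.341 with an estimated correlation and 0.0859 by fry. If less gut RNA lifted every other tissue alike, muscle and neuronal markers would rise with the testis list. In these 6 arrays the testis median exceeded that of 46 such markers (0.003) by 0.17 (bootstrap interval over genes 0.115 to 0.234). That interval holds no spread between arrays, and the testis list did not pass with an estimated correlation, so the question stays open. A larger testis share that is equal for all testis genes is argued against as the whole change. That holds only if each gene is read from testis RNA alone in whole larvae, which was not tested. Of 19 genes of the testis list with an intensity of at least 100, 17 lay above 0. These 19 differed by more than their standard errors allow (Q of 3.17 per degree of freedom). Other divisions gave at most 1.56, but they too count the group difference as spread between arrays and are no reference. The 19 include svp (0.13 ± 0.065 SE), which entered through a synonym of a listed name and was not written in the list. A larger share of some germline stages, or a change within the testis, was not tested and stays open beside the maternal diet.

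Called genes lay near each other: 37 of 107 placed genes had another called gene within 2 measured genes, against a median of 4 and a highest value of 18 in 2000 random draws matched on intensity (permutation p = 5e-04, the smallest these draws can give). Probe sets that read several family members cannot be told apart: 2 of the 37 rested on such probe sets by their suffix, but only 6 of all 117 calls did, and probe sets of several genes were not placed. Sequence variants in 1 stretch of chromosome cannot be told apart from local families: the fullest run of 50 neighbouring genes held 7 called genes, on 2R around Muc55B (95th percentile of draws 5, permutation p = 0.0015). Once direct neighbours were thinned the fullest run held 3 (permutation p = 0.986). The draws compared with it were not thinned, so that test cannot show whether crowding reaches beyond direct neighbours. Around Chd3, CG7781 and Gr32a 0 of 10 neighbouring genes each were called, around CG10073 1 (fest) and around CG3819 1 (CG6839).

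With 6 arrays there are 10 divisions into 3 and 3, too few for a share under 0.05. The real one called 117 probe sets, 107 in 1 direction, and the highest of the others called 1 in both counts, so that 1 of the 10 divisions gave as many. The others count the group difference as spread between arrays, which lowers their calls, so they are no reference for these counts. For lists past camera the real division gave 13 and the highest of the others 13, so 2 of the 10 gave as many.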
